A study of Drosophila melanogaster with 2 samples.

How the data were processed

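Chromatin immunoprecipitation with an anti-GFP antibody and sequencing was carried out by the authors in a transgenic *Drosophila melanogaster* line that stably expresses E(spl)m8-HLH fused at its C-terminus to GFP. E(spl)m8-HLH is a repressor of the Hairy/E(spl) bHLH-Orange family and a target of Notch signalling. Per the labels, chromatin came from whole embryos of both sexes aged 4 to 14 h and was sonicated to 200 to 800 bp. The samples formed 1 group of 2 biological replicates, numbered 2 and 3, with no second condition and no paired samples. Both replicates shared 1 control file, which was not analysed here.

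The files used were 4 deposited peak lists on the assembly dm6: an optimal set chosen by the authors by irreproducible discovery rate, a list called on pooled replicates, and 1 list for each replicate. The signal value of a peak is the authors' own enrichment value, taken from the deposited lists as it stands, with no recalculation from reads. The −log10 q-value is likewise the authors' value from the deposited lists. Each is a value of the peak caller and was used only to describe or rank peaks within a list. The column for the p-value held no values and was not used. The aligner, the peak caller, their versions and the threshold of the irreproducible discovery rate are not given in the sources used here. Read counts per sample are not in the files used, so depth per replicate is unknown, and the precision of each share is set by its number of peaks and is given as an interval.

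Peaks were compared with the Release 6 genome sequence and an Ensembl annotation of it, with transposable elements left out. Every peak of the 4 lists lay within the length of its chromosome arm in that sequence. The 6 arms X, 2L, 2R, 3L, 3R and 4 carried 13945 protein-coding genes and 18164 genes in all. A gene was counted as bound when a summit of the optimal set lay in its body or within 2 kb of it. A feature was assigned to each summit in the order promoter (within 500 bp of any transcription start site, TSS), exon, intron and intergenic. Summit shares by feature were compared with 1000 random placements on the same arms, for which the smallest 2-sided p is 0.002. Overlaps between the replicate lists were compared with 100 random placements of the peaks on the same arms, without a p-value.

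The 27 gene lists were fixed before the peaks were seen; they hold named genes of Notch signalling, neural and other tissues, and families chosen by symbol pattern. 5 symbols were replaced by the symbol used in the annotation, and 2 (BobB and BobC) were not found and were left out. The patterns also took in HisCl1, a histamine-gated channel, Cpr, a cytochrome P450 reductase, and Cp190 and Cp110, which are not chorion proteins; these were kept, since the patterns had been fixed. Each list was tested against other genes with a 2-sided exact test in 10 strata of gene length. Protein-coding lists were tested against protein-coding genes, and the tRNA and the snRNA and snoRNA lists against all genes. The test treats genes as independent, although neighbours can share a peak.

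Presence of 22 motifs and of all 2080 6-mers, on either strand, was compared between the window within 50 bp of each summit (101 bp) and windows of the same length 1 kb away with a 2-sided exact McNemar test. The 1538 strongest and 1538 weakest peaks of the optimal set were compared with a 2-sided Fisher's exact test. The X was compared with 2L, 2R, 3L and 3R together by an exact binomial test, with arm 4 left out. All p-values within a family of tests were adjusted by the Benjamini-Hochberg method and called at 0.05. Intervals are exact binomial or Poisson 95% intervals for shares and densities, and come from 1000 bootstrap draws for motif ratios and 200 for rank correlations. Values after ± are standard deviations of the random placements.

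Named genes were chosen by a rule fixed before the peaks were seen: the genes with the nearest TSS for the 20 strongest peaks, every gene of the E(spl) and Bearded complexes, the 4 bound members with the strongest summit and the first 3 unbound members of each list, and the 10 6-mers with the largest ratio among those past the threshold and present in at least 2% of the summit windows. A distance is from the summit to the nearest TSS, negative upstream, which is not always the TSS of the named gene. Some genes that the rule names are not reported here.

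Alternatives covered the overlap that counts as shared, stronger peaks only, flanks of 500 bp and 5 kb, summits within 1 kb of a TSS, the nearest TSS only, no strata, rotation along the gene order, promoter windows of 200 bp and 1 kb, motif windows of 25 and 100 bp, other control windows, and leaving out each replicate. Without replicate 2 or replicate 3, the optimal set was replaced by the strongest 6152 peaks of the other replicate's list. Windows within 200 bp, random windows matched in feature class and GC content at that width, and a comparison with the weaker pooled peaks were added after the data were seen. The code was tested on simulated data. Of 200 random lists of 20 genes, 2 (1%) passed 0.05, and 164 (82%) did so when the odds of being bound were raised 4-fold. A 6-mer planted in 5% of windows was found in 20 of 20 runs, and no 6-mer of 2080 passed without planting. Both sets of windows in this simulation lay 1 kb from the summits, so it did not cover the difference in GC content between summits and controls. The planted share was larger than the excess seen for CACGCG or CACGTG, and whether excesses that small would be found was not tested. Of 50 sets of random positions, 3 (6%) passed. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and bedtools 2.31.1 were used. A ratio of signal between the replicates at the E(spl) complex was computed and left out, because the signal is not scaled between lists; ranks within the replicate lists, which are of equal length, are given instead.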

Results

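The optimal set held 6152 peaks with a median width of 424 bp and a median signal of 289.8 (range 169 to 5071), and all had the same −log10 q-value of 4.21. They were the 6152 strongest of 30000 pooled peaks. Each replicate list also held 30000 peaks, with median widths of 384 bp in replicate 2 and 440.0 bp in replicate 3.

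The strongest peak lay at px on arm 2R (22514065 to 22514522), with its summit at 22514308 in an intron, 209 bp upstream of a TSS (distance −209) and a signal of 5071. CG14100 (4382, distance −87 bp), Ugalt, a UDP-galactose transporter (4057, −37 bp), and Art3, an arginine methyltransferase (3906, −128 bp), came next. E(spl)m8-HLH, the tagged gene itself, ranked 5 with 3899.8 (−147 bp). Below it stood cbt (3836, −1373 bp, within an intron of ush), CG11050 (3758, 1017 bp), the Polycomb group gene ph-p (3742, −461 bp), the mitochondrial ribosomal protein gene mRpL41 (3458, −139 bp) and CG18549 (3310.4, −133 bp). Fkbp14 (3196, −124 bp), Chro, which encodes Chromator (3125, 76 bp), CG1888 (3067, −246 bp), E(spl)m7-HLH (3034, −294 bp) and CG31668 (3022, 3767 bp) followed. The 20 strongest ended with hll (2971, −2911 bp), CG11309 (2890.3, 85 bp), E(spl)mbeta-HLH (2852, −117 bp), the kinase gene Lk6 (2842, −973 bp) and CG32772 (2842, 1273 bp). Of these 20 summits, 14 lay within 500 bp of a TSS and 3 belonged to E(spl) genes. All 20 were in both replicate lists, at rank 64 or better in replicate 2 and 33 or better in replicate 3.

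All 12 genes of the E(spl) complex were bound, against 3.04 expected for genes of their length (3.94-fold, exact adjusted p 5.5e-07). Between 25995621 and 26051911 on 3R the complex held 41 peaks, with a median signal of 611 against 289.8 for the whole optimal set, and 9 of the 100 strongest peaks. By rank within each replicate's own list, counted after the pooled values were seen, the complex held 5 of the 100 strongest peaks in replicate 2 and 11 in replicate 3, and 38 and 41 of the strongest 6152. The strongest peak at E(spl)m8-HLH and the neighbouring corepressor gene gro spanned 26039132 to 26040891, with its summit at 26040093; it ranked 1 in replicate 3 and 21 in replicate 2. The strongest peaks at E(spl)m6-BFM, E(spl)m7-HLH and E(spl)m5-HLH ranked 3, 4 and 9 in replicate 3 and 154, 64 and 58 in replicate 2. The other bHLH genes reached 3034 at E(spl)m7-HLH, 2852 at E(spl)mbeta-HLH, 2762 at E(spl)m5-HLH, 1907 at E(spl)mgamma-HLH, 1321 at E(spl)mdelta-HLH and 774 at E(spl)m3-HLH. The Bearded family genes of the complex reached 2767 at E(spl)m6-BFM, 819 at E(spl)malpha-BFM, 775 at E(spl)m2-BFM and 537 at E(spl)m4-BFM. The summit counted for E(spl)m6-BFM was nearest to the TSS of E(spl)m7-HLH (−2024 bp), and that for E(spl)mdelta-HLH to that of CG43116. In the separate Bearded complex on 3L, Brd was bound (316, −208 bp) and BobA, Ocho and Tom were unbound, 1 of 4 against 0.858 expected (exact adjusted p 1). No other window of this length held more than 22 peaks, with a mean of 2.58 over 133433 windows moved in steps of 1 kb. The 12 genes are neighbours that share peaks, so they are not 12 independent cases. Under rotation along the gene order, which keeps neighbours together, the excess was 2.58-fold and only just passed (permutation adjusted p 0.0498), and over the other alternatives it ran from 2.46-fold with flanks of 5 kb to 6.69-fold with summits within 1 kb of a TSS. Reads from a transgenic copy of E(spl)m8-HLH would map to the native gene, and the extent of the transgene is not given in the sources used here.

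**Figure D1:**
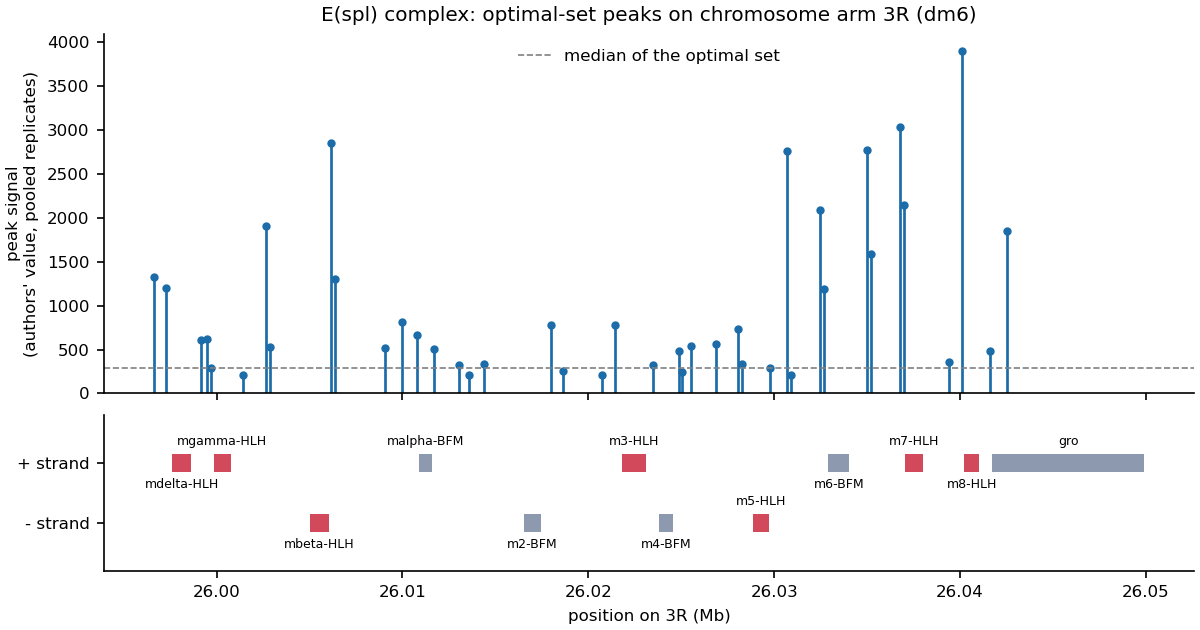
Peaks of the optimal set across the E(spl) complex on arm 3R, with the genes of the complex. Height is the signal value of the deposited list.

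Of 19 genes of the sensory organ precursor, 18 were bound against 10.5 expected (1.72-fold, exact adjusted p 0.00104). The strongest of them were cpo (1829), the cell fate determinants numb (1669.8) and pros (1638), and spdo (1479), and only sca was unbound. The excess ran from 1.56-fold with flanks of 5 kb and 1.57-fold without replicate 3 (adjusted p 0.0154) to 2.62-fold under rotation along the gene order and 2.63-fold with summits within 1 kb of a TSS. Of 20 neuroblast genes, 17 were bound against 9.69 expected (1.75-fold, exact adjusted p 0.00373), led by brat (1647), grh (1408), wor (927) and D (649), with cas, dpn and ind unbound. The neuroblast call was lost when a summit had to lie within 1 kb of a TSS, at a like excess (1.78-fold, adjusted p 0.111), and without replicate 3 (1.40-fold, adjusted p 0.203).

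Other lists of neural genes and of Notch signalling did not pass the threshold. Among proneural genes and da, 4 of 8 were bound against 2.31 expected (exact adjusted p 0.541): cato (741), da (418), ato (359.7) and ase (316), while ac, amos and l(1)sc were unbound. Of 20 Notch pathway components, 12 were bound against 10.3 expected (exact adjusted p 0.844), led by numb (1669.8), spdo (1479), neur, a ubiquitin ligase for Delta (1463), and mam, a coactivator (1095), with CtBP, H and Psn unbound. Of 6 other bHLH-Orange repressor genes, Hey (357), hry (296) and cwo (261) were bound against 2.47 expected, and Sidpn, dpn and her were unbound (exact adjusted p 1). Among neuronal genes, 10 of 16 were bound against 9.57 expected (exact adjusted p 1), led by elav (1921), ChAT (567), ham (443) and CadN (406), with Appl, Syt1 and brp unbound. Glial genes gave 10 of 13 against 6.37 expected (exact adjusted p 0.130), led by pnt (728), moody (611), repo (559) and Gli (464), with Eaat1, alrm and gcm unbound. Midline genes gave 6 of 9 against 4.55 (exact adjusted p 0.774), led by sim (1697), spi (678), sli (361) and oc (285), with btd, tgo and vvl unbound. The summit counted for da was nearest to the TSS of Cdk1. Counted by nearest TSS only, the midline (2.38-fold), proneural (3.66-fold) and Bearded complex lists (5.80-fold) passed, and glial genes passed under rotation (2.05-fold), without strata (2.09-fold) and without replicate 2.

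Ribosomal protein genes were bound in 73 of 88 cases (83.0%) against 25.3 expected, 2.88-fold (exact adjusted p 5.7e-25). The ratio ran from 1.92 with flanks of 5 kb to 4.50 by nearest TSS. RpL3 (1192, at the TSS of CG17726) and RpL7 (1074) were among those with the strongest summits, and RpL10Aa, RpL10Ab and RpL15 were unbound. Of 301 snRNA and snoRNA genes, 134 (44.5%) were bound against 66.5 expected, 2.01-fold (exact adjusted p 1.8e-20). The strongest were scaRNA:MeU5-C46 and snRNA:7SKa, which share 1 summit of 2133, snoRNA:Me28S-U3344a (1491) and snoRNA:Me18S-A1374 (1038), and scaRNA:MeU2-48, scaRNA:MeU2-C41 and scaRNA:MeU2-G25 were unbound. The shared summit lay 175 bp upstream of the TSS of CG1142. With flanks of 500 bp the ratio for snRNA and snoRNA genes was 1.35 and the call was lost (adjusted p 0.246), and it was 1.31 under rotation and 1.3 without strata. Of 295 tRNA genes, 86 (29.2%) were bound against 65.3 expected, 1.32-fold (exact adjusted p 0.00733), led by tRNA:Val-CAC-2-3 and tRNA:Val-CAC-2-4, at the same summit of 2133, and by tRNA:Val-TAC-1-1 and tRNA:Val-TAC-1-2 (1461), with tRNA:Ala-AGC-2-10, tRNA:Ala-AGC-2-11 and tRNA:Ala-AGC-2-2 unbound. The tRNA call was lost under 4 alternatives and its direction turned under 3, to 0.853 without strata of gene length.

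Histone genes were bound in 5 of 118 cases against 23.0 expected (0.218-fold, exact adjusted p 6.4e-06), and 3 of the bound ones were the replication-independent His3.3B (356), His2Av (325) and His3.3A (229), beside the channel gene HisCl1 (362). The summit counted for His2Av was nearest to the TSS of ball and that for HisCl1 to that of prd1. The 3 His1 copies named by the rule were unbound and lay near each other on 2L, so such copies are not independent cases. Under rotation along the gene order, which keeps neighbours together, histone genes were at 0.116 of expectation (permutation adjusted p 0.027). How reads from repeated genes were placed is not given in the sources used here. Cuticle protein genes gave 10 of 114 against 31.2 expected (0.321-fold, exact adjusted p 4.2e-06), with Cpr76Ba (736, without a peak in replicate 3), Cpr31A (450.3), Cpr73D (317) and Cpr64Aa (258) strongest and Cpr, Cpr11A and Cpr11B unbound. The summit counted for Cpr31A lay in an intron of Pen. Odorant and gustatory receptor genes gave 12 of 179 against 59.4 expected (0.202-fold, exact adjusted p 9.5e-17). Or85f (960), Ir68b (871), Gr97a (602) and Gr89a (494) were the strongest, and Gr10a, Gr10b and Gr21a were unbound. The summits counted for Or85f, Ir68b and Gr97a were nearest to the TSS of RpL34b, yps and Tsp97E. Without strata histone genes were at 0.115 of expectation; cuticle genes were at 0.0978 with flanks of 500 bp and 0.473 with flanks of 5 kb, and receptor genes at 0.0256 with summits within 1 kb of a TSS and 0.372 with flanks of 5 kb. Chorion and vitelline genes gave 2 of 23 against 6.60 expected (exact adjusted p 0.0905), and these were Cp190 (1629), which is not a chorion gene, and the yolk protein gene Yp3 (445); Cp110, Cp15 and Cp16 were unbound. The summits counted for Cp190 and Yp3 were nearest to the TSS of CG4338 and rdgB. The deficit of chorion and vitelline genes passed with flanks of 5 kb (0.296), by nearest TSS and without strata (0.236).

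Lists for other tissues and pathways did not pass the threshold with flanks of 2 kb and strata of gene length. Mesoderm and muscle genes were bound in 12 of 20 cases against 10.5 expected (exact adjusted p 0.862), with Mef2 (2523), kirre (1402, with 21 summits), tin (1036) and bin (1035) strongest and Act57B, Mhc and bap unbound. The summit counted for Mef2 lay in an intron of Pal1, nearest to the TSS of Pdrg1. EGF receptor pathway genes gave 14 of 17 against 9.52 (exact adjusted p 0.0905), led by the inhibitor aos (1628), Raf (1439), S (1234) and aop (1037), with Sos, kek1 and rl unbound. Genes of Dpp, Hedgehog and Wingless signalling gave 17 of 22 against 11.6 (exact adjusted p 0.0745), led by fz (1672), Med (1520.1), Mad (1377) and gbb (1179), with pan, sax and scw unbound; the summit for Med was nearest to the TSS of Mnat9 and that for gbb to that of eIF6. All 8 Hox genes were bound against 5.06 expected (exact adjusted p 0.103), led by Antp (680.2), Abd-B (548), lab (518) and Ubx (416). Cell cycle genes gave 11 of 16 against 6.85 (exact adjusted p 0.116), led by CycB (2614), CycE (961), fzr (919) and E2f1 (823), with Cdk2, CycA and CycD unbound. The summit counted for fzr was nearest to the TSS of CG3009. Some of these lists for other tissues and pathways passed under alternatives. Dpp, Hedgehog and Wingless genes passed under 6 of 9, among them rotation (2.22-fold), without replicate 2 (1.53-fold) and without replicate 3 (1.51-fold), and EGF receptor genes under 5 of 9, among them rotation (2.24-fold). Hox and cell cycle genes each passed under 3: nearest TSS (1.87-fold and 1.94-fold), rotation (2.59-fold and 1.85-fold) and no strata (2.71-fold and 1.87-fold). Hox genes turned to 0.336 of expectation with summits within 1 kb of a TSS and were at 1.1-fold in the stronger 50% of peaks and 1.24-fold without replicate 2.

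Segmentation genes were bound in 9 of 21 cases against 9.13 expected (exact adjusted p 1), with slp1 (1032), ptc (710.1), hb (307) and opa (281) strongest and en, eve and ftz unbound. Counted by nearest TSS only, segmentation genes were 2.22-fold and tracheal genes 1.76-fold over the expected number. Tracheal genes otherwise gave 7 of 13 against 7.23 (exact adjusted p 1), led by grh (1408), rib (913), trh (724) and dysf (421), with btl, kni and salm unbound. Endoderm and fat body genes gave 7 of 13 against 6.15 (exact adjusted p 1), led by Hnf4 (699), Lsp2 (697), fkh (688) and lab (518), with Fbp1, Fbp2 and GATAe unbound. Blood cell genes gave 4 of 12 against 6.09 (exact adjusted p 0.541): ush (3836), srp (290.1), lz (255) and Pxn (200.4), with Hml, NimC1 and PPO1 unbound. Germ line genes gave 6 of 12 against 5.34 (exact adjusted p 1), led by bgcn (592), Sxl (442), gcl (273) and vas (238), with aub, bam and osk unbound. The summits counted for Lsp2, Pxn, gcl and vas were nearest to the TSS of DEF8, MEP-1, CG14767 and solo. In all, 5137 of 13945 protein-coding genes (36.8%) and 6207 of all 18164 genes (34.2%) were bound.

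**Figure D2:**
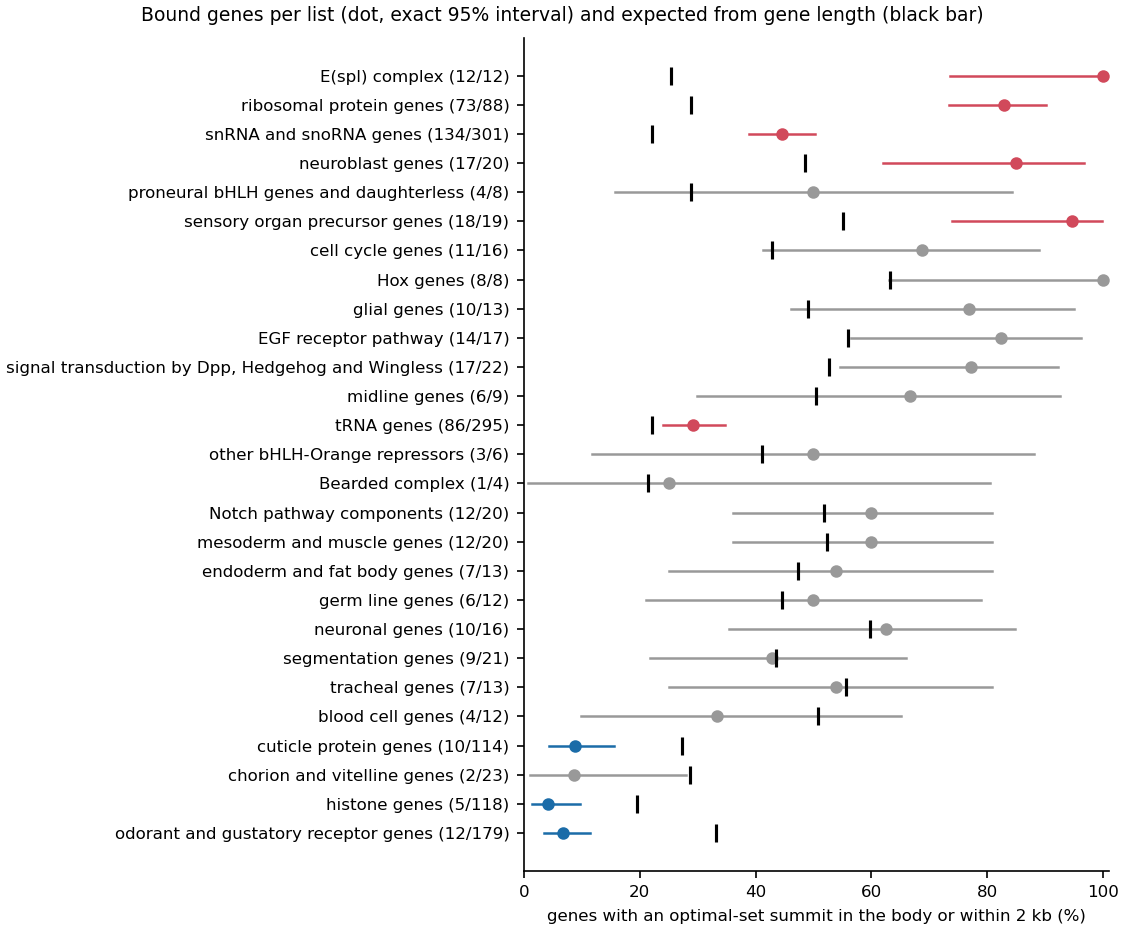
Share of bound genes in each of the 27 lists, with exact 95% intervals, and the share expected from gene length. Red, more than expected; blue, fewer; grey, not past the threshold.

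Promoters held 2474 summits, 40.2% (39.0 to 41.5) against 13.6 ± 0.444% of random placements (2.95-fold). Exons held 176 (2.86% against 19.7%, 0.145-fold), intergenic DNA 1161 (18.9% against 27.3%, 0.690-fold) and introns 2341 (38.1% against 39.4%, 0.967-fold, permutation p 0.038). For the other 3 features the permutation p was 0.002, the smallest that these placements can give. With a promoter window of 200 bp introns were at 1.06 times the random share, and in the stronger 50% of peaks the intron deficit was no longer called (0.964, permutation p 0.0899). Promoters were at 4.50 times the random share with that narrower window. Of 2279 summits within 500 bp of a protein-coding TSS, 1825 (80.1%) lay upstream and 454 downstream, with a median of −114 bp, and 1571 of all summits (25.5%) were over 5 kb from one. The 23848 weaker pooled peaks lay in promoters in 26.9% of cases (1.98-fold), in introns in 42.3%, in intergenic DNA in 24.1% and in exons in 6.68%.

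Arm 4 had 12.8 peaks per Mb (7.44 to 20.4; 17 peaks) and arm 2L 52.0 (49.1 to 55.0; 1223 peaks). Between these were X with 41.8 (39.3 to 44.5; 982 peaks), 2R with 43.2 (40.7 to 45.8; 1092 peaks), 3R with 46.1 (43.8 to 48.5; 1477 peaks) and 3L with 48.6 (46.1 to 51.3; 1361 peaks). The X had 0.884 times the density of 2L, 2R, 3L and 3R together, with arm 4 left out (2-sided exact binomial p 3.3e-04). The test takes peaks as independent, and since peaks cluster this p is too small.

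The Hairy/E(spl) class C site CACGCG lay within 50 bp of 3.32% of summits against 2.13% of windows 1 kb away, a ratio of 1.56 (1.25 to 1.91; adjusted p 2.2e-04). The E-box CACGTG, bound by the same family, was at 2.00% against 1.41% (1.41, 1.09 to 1.86; adjusted p 0.0367). The CACGTG call was lost with windows of 25 bp (1.44, adjusted p 0.173) and without replicate 3 (1.11, adjusted p 0.587), and the CACGCG call among the stronger 50% of peaks (1.21, adjusted p 0.359), where CACGTG was at 2.18. Against random windows of the same feature class and GC content, CACGTG was at 2.41 and CACGCG at 2.65. ATCGATA, the core element of DREF and BEAF-32, was at 2.60% against 1.15% (2.25; adjusted p 1.5e-08), but at 0.886 times the control share for summits over 1 kb from a TSS, 1.74 times without replicate 2 and 3.43 times without replicate 3. Other motifs above control were TAATTA, a homeodomain site (9.85% against 6.37%, 1.55; adjusted p 1.2e-11), CATATG (4.14% against 2.97%, 1.39; adjusted p 0.00121), AGATAA, a GATA factor site (7.93% against 5.98%, 1.33; adjusted p 1.0e-04), and AAAAAA (25.1% against 18.3%, 1.37; adjusted p 2.4e-18). Against the matched windows TAATTA (0.956), AGATAA (0.982) and AAAAAA (0.934) turned below control, as they did against dinucleotide shuffles (0.818, 0.855 and 0.852). The CATATG call was lost with windows of 25 bp (1.24), for summits over 1 kb from a TSS (1.28) and without replicate 2 (1.24, adjusted p 0.0501). CACCAG (1.93% against 4.39%, 0.441; adjusted p 6.3e-14) and CAGGTG, an E-box of proneural factors and Snail (2.88% against 4.19%, 0.686; adjusted p 2.6e-04), were below it. CAGGTG turned to 1.19 against the matched windows and 1.33 against shuffles, and lost its call in the stronger 50% (0.752) and over 1 kb from a TSS (0.939); CACCAG lost its call against shuffles (0.908). The tests were exact and 2-sided over 6152 pairs of windows.

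The remaining motifs did not pass against windows 1 kb away. Among them were the Suppressor of Hairless sites TGGGAA (0.880) and GTGGGAA (0.871) and the E-boxes CAGCTG (0.968), CAGATG (0.872) and CACATG (0.909). CAGGTAG (1.14), GAGAGA (0.964), ACAATG (1.06), AACCGG (0.855) and CCCGGG (0.609, exact adjusted p 0.0976) did not pass either. Nor did CACGAG (0.962), CACAAG (1.00) and CACTAG (1.21), which were fixed beforehand as candidate Hairy/E(spl) sites together with CACCAG (0.441, below control). Of the candidate Hairy/E(spl) sites, only CACGCG and CACGTG passed above control within 50 bp against windows 1 kb away. The Suppressor of Hairless sites gained calls below control under some alternatives (TGGGAA under 3, GTGGGAA under 2) and turned above control against shuffles. Against matched windows within 50 bp, CAGCTG (1.82), GAGAGA (1.54), CACATG (1.33) and CAGATG (1.28) passed above control. Summit windows had 35.0% GC against 42.6% in the control windows. Against random windows of the same feature class and GC content, within 200 bp, CACGCG was at 11.9% against 6.32% (1.88, 1.69 to 2.13) and CACGTG at 6.92% against 4.47% (1.55, 1.34 to 1.79). Under the same matching CAGCTG (22.1% against 13.5%, 1.64) and GAGAGA, bound by the GAGA factor (23.6% against 13.9%, 1.70), rose above control, with CAGGTAG, the Zelda site, at 1.69, ATCGATA at 1.63 and CACGAG at 1.41. At this width CACCAG was below control at 0.886 and CAGGTG at 0.809, TAATTA stood at 0.991, and the AGATAA call was lost (1.05). The match on GC content at this width was chosen after the first values were seen.

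**Figure D3:**
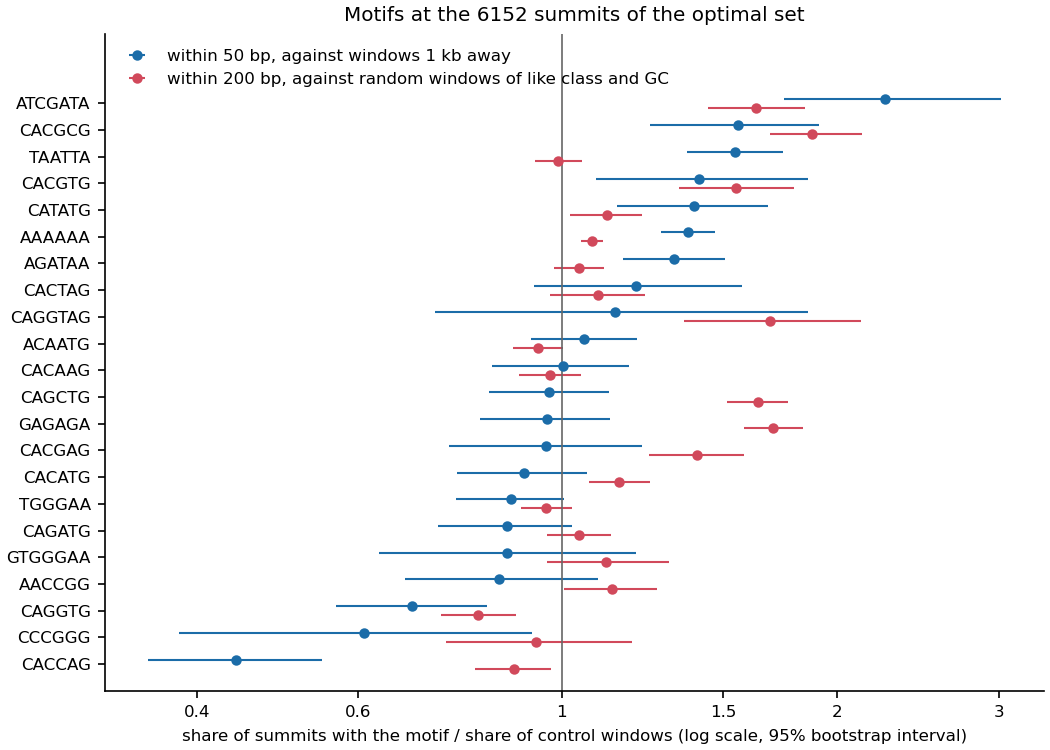
Ratio of the share of summit windows with each motif to the share of control windows, with 95% bootstrap intervals. Blue, within 50 bp against windows 1 kb away; red, within 200 bp against random windows of the same class and GC content.

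Of all 6-mers, 409 were more frequent and 952 less frequent near summits than 1 kb away. The 10 with the largest ratios were ATATTA (19.6% of windows against 8.31%, 2.36), CTAGTA (2.30), AATATT (2.25), AATATA (2.18), TATTAA (2.10), ATAGTA (2.10), ATAATA (2.10), TAGTAA (2.08), ATATAA (2.07) and TAGCTA (2.05). Of 228 6-mers with at least 5 A or T bases, 222 were more frequent, and of 720 with at most 2, only 2 were. GC content was 34.8% within 40 bp of the summit, 42.2% at 80 to 200 bp and 42.4% at 600 to 800 bp. GAGAG was found at 30.8, 66.0 and 38.3 per 1000 peaks and bin of 20 bp at these distances, AATATT at 44.9, 19.6 and 18.2, and ATCGATA at 8.41, 9.17 and 3.25. CACGTG stood at 4.51, 3.44 and 2.65, CACGCG at 7.48, 6.35 and 5.30, and CAGCTG at 10.9, 14.7 and 10.2. Within 200 bp and with matched GC content, 397 of the 6-mers were more frequent and 536 less frequent. There GCGCGC (1.90), CACGCG (1.88), ACAGTG (1.78), GTGCAC (1.77) and ACACTG (1.76) had the largest ratios.

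**Figure D4:**
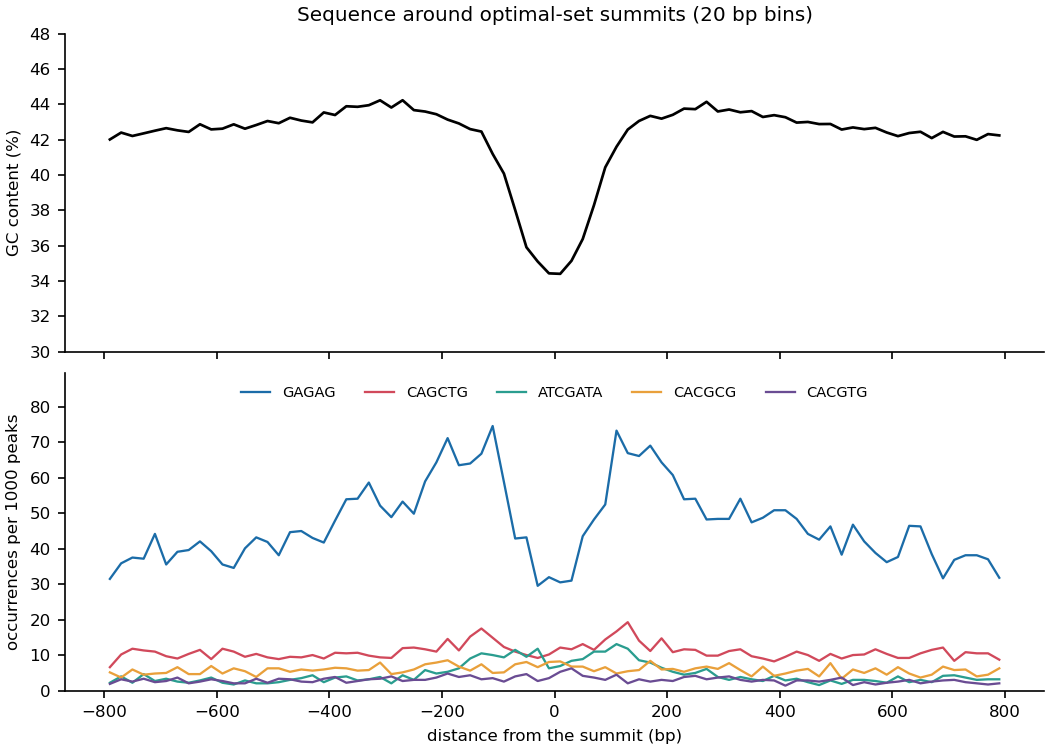
GC content and motif frequency by distance from the summits of the optimal set.

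Among the 1538 strongest peaks 71 (4.62%) had CACGTG or CACGCG within 50 bp, against 99 (6.44%) of the 1538 weakest, a difference of −1.82 points (2-sided exact adjusted p 0.0329). The call was lost without replicate 3 (−1.30 points, adjusted p 0.0906) and for the stronger against the weaker 50% of peaks (−1.11 points, adjusted p 0.0580), and without replicate 2 the difference was 0.0650 points (adjusted p 1). The site comparison was not matched for GC content. Relative to DNA farther away, GC content fell more at the summits of the strongest peaks (−10.5 points) than of the weakest (−4.64). Both sites are rich in G and C, so the comparison cannot separate fewer sites from a difference in base composition. Promoters held 694 of the strongest (45.1%) and 586 of the weakest (38.1%), a difference of 7.02 points (exact adjusted p 1.8e-04). It was 1.63 points without replicate 2 (adjusted p 0.764), where the call was lost, and 3.38 points for the stronger against the weaker 50%.

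Of 30000 peaks in replicate 2, 21232 (70.8%, 70.3 to 71.3) overlapped a peak of replicate 3, against 15.0 ± 0.210% of random placements (4.73-fold). In the other direction 23183 (77.3%, 76.8 to 77.7) overlapped, 4.84 times the random share. The highest share among the random placements was 15.5% for replicate 2 and 16.5% for replicate 3. Among the 6152 strongest of each list, 78.2% of replicate 2 and 81.4% of replicate 3 peaks overlapped, 25.3 and 25.6 times the random share. Signal ranks of 21232 overlapping pairs correlated with a Spearman coefficient of 0.723 (0.713 to 0.731). The optimal set overlapped replicate 2 at 6124 peaks (99.5%) and replicate 3 at 6085 (98.9%), and 5459 (88.7%) and 5313 (86.4%) of its peaks met one of the strongest 6152 there. The optimal set was made from the same replicates, so these last shares follow from how it was chosen.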

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

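The ±200 bp windows, the same windows matched in class and GC content, and the comparison with the weaker pooled peaks were chosen after seeing the data; the other alternatives were planned. Over gene lists, 181 of 241 values kept their direction and side of the threshold, 7 lost the call, 26 gained one and 27 turned; over motifs 155 of 264 kept both, 10 lost, 28 gained and 71 turned or stood at a ratio of exactly 1, most with no call either way. The cause was not tested for any change below. Replicate overlap (70.8%) was 60.2% at 50% reciprocal overlap, 53.2% for summits within 100 bp, 74.8% for the stronger 50% and 80.6% for the strongest 1000 peaks. The rank correlation between replicates (0.723) was 0.734 over the optimal set, 0.788 for summits within 100 bp and 0.756 for the stronger 50%. The share of the optimal set found in replicate 2 (99.5%) was 87.7% at reciprocal overlap and 97.2% for summits. With promoters of 200 bp introns turned to 1.06; promoters stayed in excess throughout and were 1.49 times as frequent as in weaker pooled peaks. Gene lists above expectation (6) were 13 by nearest TSS, 10 under rotation, 10 without strata, 6 with flanks of 5 kb, 6 in the stronger 50%, 5 with flanks of 500 bp, 4 with summits within 1 kb of a TSS, 8 without replicate 2 and 5 without replicate 3. Lists that turned were, under rotation, Bearded (0.652), segmentation (1.16), tracheal (1.44) and tRNA (0.846); without strata, the same (0.679, 1.16, 1.46 and 0.853). With summits within 1 kb of a TSS neuronal (0.521), mesoderm (0.610), Hox (0.336) and endoderm lists (0.514) turned, and by nearest TSS neuronal (0.890), segmentation (2.22), tracheal (1.76) and germ line lists (0.837). In the stronger 50% neuronal (0.893), tracheal (1.01), germ line (0.595) and tRNA lists (0.966) turned, and tracheal genes also with flanks of 5 kb (1.07) and 500 bp (1.11). With each replicate left out, lists that turned ranged from 0.871 to 1.02 (neuronal), 0.734 to 1.25 (segmentation), 0.939 to 1.15 (tracheal), 0.940 to 1.19 (endoderm) and 0.977 to 1.07 (germ line). Motifs above control (7) were 11 against dinucleotide shuffles; motifs below (2) were 6 with 100 bp windows, 4 with controls 500 bp away, 4 against shuffles, 4 in the stronger 50%, 4 at ±200 bp and 2 to 5 when each replicate was left out. CACGTG lost its call with 25 bp windows (1.44) and ranged from 1.11 to 1.76 when each replicate was left out; CACGCG lost it in the stronger 50% (1.21). Motifs turned against shuffles: CACGAG (1.31), CACAAG (0.878), CAGCTG (4.45), CAGGTG (1.33), CAGATG (1.29), TGGGAA (1.54), GTGGGAA (2.39), GAGAGA (2.00), ACAATG (0.819), AACCGG (1.09), AGATAA (0.855), TAATTA (0.818) and AAAAAA (0.852). Against matched windows CACGAG (1.28), CAGCTG (1.82), CAGGTG (1.19), CAGATG (1.28), CACATG (1.33), TGGGAA (1.11), GTGGGAA (1.4), GAGAGA (1.54), ACAATG (0.938), AACCGG (1.23), AGATAA (0.982), TAATTA (0.956), AAAAAA (0.934) and CCCGGG (1.33) turned. At ±200 bp CACGAG (1.09), CACAAG (0.97), CAGCTG (1.2), GTGGGAA (1.00), GAGAGA (1.52) and ACAATG (0.980) turned, and with matching CACGAG (1.41), CACAAG (0.972), CAGCTG (1.64), CAGATG (1.04), CACATG (1.15), GTGGGAA (1.12), GAGAGA (1.70), ACAATG (0.943), AACCGG (1.13) and TAATTA (0.991). At 25 bp CACGAG (1.03), CAGCTG (1.02) and CAGGTAG (0.900), at 100 bp CACAAG (0.923), CAGCTG (1.03), GAGAGA (1.25) and ACAATG (0.95), and with controls 500 bp away CACAAG (0.938), CAGCTG (1.1), CAGATG (1.02), CAGGTAG (0.870) and ACAATG (0.943) turned. In the stronger 50% CACAAG (0.954), GAGAGA (1.24) and ACAATG (0.858) turned, and over 1 kb from a TSS CACGAG (1.08), CAGATG (1.16), CACATG (1.00), GAGAGA (1.16) and ATCGATA (0.886). With each replicate left out, motifs that turned ranged from 0.799 to 1.03 (CACGAG), 0.888 to 1.19 (CACAAG), 0.938 to 1.14 (CAGCTG), 0.783 to 1.00 (GTGGGAA), 0.964 to 1.27 (GAGAGA), 0.927 to 0.936 (ACAATG) and 0.756 to 1.00 (AACCGG). Less frequent 6-mers (952) were 536 at ±200 bp with matching. The site difference between strong and weak peaks (−1.82 points) lost its call for the stronger against the weaker 50% (−1.11) and whenever a replicate was left out (−1.30 to 0.0650), and the promoter difference (7.02) ranged from 1.63, with its call lost, to 9.04. Ranking by −log10 q-value was not run, since all optimal peaks are tied, and the nearest TSS was not used for tRNA, snRNA and snoRNA genes. No paired analysis was possible because there is 1 group. Read depth is unknown, so what it limits was not assessed.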

Other observations

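The tests of displaced summits, of distal summits, of weak against strong peaks and of random positions in host genes, and the 12 gene families, were chosen only after the results were seen; the remaining tests were chosen before. Of 6 families of genes of differentiated or adult tissues, taken by symbol pattern with the prediction of few peaks written before their values, 4 were bound less often than genes of their length: cytochrome P450s in 6 of 85 cases (30.6 expected, exact adjusted p 4.1e-09), Jonah proteases and trypsins in 0 of 27 (6.35 expected, exact adjusted p 0.00320), Osiris genes in 1 of 25 (8.60 expected, exact adjusted p 0.00242) and mucins in 0 of 13 (5.58 expected, exact adjusted p 0.00320). Seminal fluid proteins (4 of 47, exact adjusted p 0.141) and glutathione S-transferases (7 of 35, exact adjusted p 0.683) did not pass. Rotation along the gene order was not run for these families, so any neighbouring members were counted as independent cases.

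The fall in GC content at summits has 3 hypotheses tested here. If summits lay to one side of the bound sites, GAGAG should be more frequent midway between 2 neighbouring summits than outside them; the ratio was 1.57 (0.665 to 5; 78 pairs, 14.1% against 8.97%, exact McNemar p 0.481), so the test could not tell. If AT-rich promoter DNA were the whole cause, the fall should vanish for summits over 1 kb from a TSS; it was −5.12 points (−5.52 to −4.72; 3368 summits, 35.3% against 40.4%), against −10.1 within 1 kb, so promoters cannot be the whole cause. If a bias towards low GC content lifted weak peaks over the threshold, the fall should be deeper in weak peaks. It was −4.64 points in the 1538 weakest and −10.5 in the strongest. The excess depth of the weakest over the strongest was therefore negative, −5.82 points (−6.73 to −4.92), against that prediction. The strongest lay more often at promoters (45.1% against 38.1%), where the fall was deeper. A gap of 7.02 points in that share could account for only a small part of the difference in depth. Such a bias is still not excluded, since all of these peaks had passed the threshold. Nor is a bias that raises strong peaks excluded. Without the control's reads a bias of sequencing or mapping might remain.

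Binding at ribosomal protein genes may come with Hairy/E(spl) sites in their promoters, a biological hypothesis. CACGTG or CACGCG was found within 200 bp of the summit in 33 of 90 ribosomal protein promoter peaks (36.7%) and 414 of 2384 others (17.4%), a ratio of 2.11 (1.59 to 2.81; Fisher's exact p 1.8e-05), which fits. The windows were alike in mean GC content (39.2% against 38.8%), so matching on it could hardly change the ratio. Against promoter peaks of like GC content (17.0%) the ratio was 2.16 (1.51 to 2.92), which adds little to the first comparison. Binding at widely expressed genes in general, a technical explanation where open promoters attract any antibody, predicted an excess in most of 6 families and was seen in 1: mitochondrial ribosomal proteins (44 of 73, 17.9 expected, exact adjusted p 9.1e-10), but not complex I (14 of 40), proteasome (16 of 49), translation initiation factors (19 of 44), chaperonin (2 of 8) or Sm and Prp proteins (7 of 18). The smaller families could miss a modest excess, with intervals of 3.19 to 65.1% bound for chaperonin and 17.3 to 64.3% for Sm and Prp proteins. The control file was not analysed, so attraction of any antibody by open promoters was not excluded. Recruitment through other promoter factors was not tested.

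Binding at snRNA and snoRNA genes might only reflect their hosts. Of 166 such genes inside bound protein-coding genes, 100 (60.2%) were bound. Random positions in the same genes were near a summit in 57.5% of cases (51.8 to 63.3), so the small RNA genes stood out little from other positions there. A summit near a small RNA gene also makes its host count as bound, so the test cannot tell which of them accounts for the binding. Of the 135 elsewhere, 34 (25.2%) were bound, a share lowered by construction, since a gene inside an unbound gene cannot be bound. An earlier test on genes outside bound hosts was dropped, since its outcome was fixed by its construction, and no biological explanation was tested.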
